A study of Rattus norvegicus with 20 samples.

How the data were processed

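The data are 20 rat arrays of 43628 spots, scanned in 2 colours, from 10 animals with 2 dye-swapped arrays each. Each array compares sprouting with non-sprouting neurons of 1 animal, and 5 animals belong to day 7 and 5 to day 21. Per the file headers, the scanner files were made with Agilent Feature Extraction 9.1.3.1 and hold, as intensity, the mean signal and median local background of every spot in both channels. They also hold processed signals, an intensity from which, per the file headers, a fitted spatial surface was subtracted and which were dye-normalized by a linear and a lowess step. The authors also deposited a table of normalized log2 ratios, Cy5 over Cy3, not turned for the dye swap, whose method is not stated. Of its columns 20 were used as an alternative, with 75 missing values, and 20 columns of mean log intensity were not used. Each of the 20 ratio columns correlated best with the loess ratio of its own array. The labels give the animal, day and dye of each array. Cohorts of the days were separate, so replicate numbers do not pair animals.

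The mean signals were corrected for local background with normexp at an offset of 50, and ratios were normalized within each array by loess, with 2256 control spots at weight 0 and spots marked as outliers left out (limma 3.58.1 in R 4.3.3). Ratios were turned to sprouting over non-sprouting, spots of a probe were averaged, and both arrays of an animal were averaged to 1 value per animal. A probe was kept if it lay well above background on at least 0.5 of the arrays of at least 1 cell type and day and was measured in at least 3 animals per day. Of 41012 probes 37345 passed the brightness filter and 37343 both. The brightest probe stood for a gene, which left 33089 genes, 14448 of them with a gene symbol and 31821 measured in all 10 animals. Array names were matched to current symbols with the table of the GRCr8 assembly, used for names only: 10658 probes by accession, 4654 by symbol and 3886 by synonym, while 21814 kept the name in the file. No chromosome positions are given for this reason.

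Ratios were tested with limma lmFit and eBayes in a single fit with a mean per day, so that both days share the spread between animals (2.23 prior degrees of freedom). The contrasts were day 7, day 21, the mean of both days, and the difference of day 21 minus day 7. All tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Within a cell type, day 21 was compared with day 7 on channel levels after Aquantile normalization between arrays, with 5 against 5 animals. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, on genes measured in all 10 animals. The p-values were adjusted over 27 lists per contrast, and members were also counted adjusted over the list alone. The 18 gene lists cover growth-associated genes, axon guidance, growth-inhibitory receptor signalling, chondroitin sulfate proteoglycans, growth factors, chromatin regulators, immediate early genes, cytoskeleton, presynaptic release, glutamate and GABA receptors, ion channels, oxidative phosphorylation, ribosomal proteins, heat shock, inflammation, apoptosis, cholesterol synthesis and adhesion. The 9 marker lists cover astrocytes, oligodendrocytes, microglia, endothelial and mural cells, blood, GABAergic interneurons, glutamatergic projection neurons, and upper and deep cortical layers. List medians per animal were compared by exact tests, sign flips of animals within a day or over both days and permutation of animals between days. With 5 animals the smallest two-sided exact p is 0.0625, so that no exact test within a day can pass. Between days and over both days, a single list at the smallest exact p cannot pass the correction over 27 lists on its own.

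The lists, tests, filters, thresholds and most alternatives were chosen before the data were examined. So was the rule for named genes. Per contrast it takes up to 10 genes in each direction past the threshold with the same sign in every animal, and remaining places go to the smallest unadjusted p with the same sign in every animal. It adds up to 4 members of each list with the smallest p and a fixed set of genes known from axon growth. For the difference between days no condition on the sign was set, and within a cell type up to 5 genes per direction were taken among those whose animals did not overlap between days. Names that are only an accession or a clone were skipped. Where the text names a gene outside the rule, it says so.

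Alternatives were no background subtraction, the processed signals centred on their median, median centring in place of loess, scaling between arrays, the deposited ratios, and outlier spots kept. Others were no filter or a stricter filter, all probes or their mean, moderation with a trend, array weights, a fit per day, 20 arrays with the animal as a random block and a dye term, scan day as a block, replicate number as a block, a threshold of 0.1, and leaving out each animal in turn. For levels within a cell type the 75th percentile was used in place of Aquantile. Chosen after seeing the data were an oligodendrocyte covariate, lists without shared members, scan day as a block for lists and for levels within a cell type, replicate number as a block for lists, the threshold of 0.1 for levels within a cell type, and other processing for the agreement of dye-swapped arrays. The pipeline was tested on simulated data with the animals' own spread, with every gene drawn independently. Each run with changed genes also held 100 genes changed by a larger size, 1 or, within a cell type, 2. Recovery may be lower where genes move together or fewer genes change. Of 100 genes changed by 0.5 on the log2 scale 82 were recovered at day 7, 81 at day 21 and 95 over both days, with 15, 6 and 8 false calls among 33089 genes, and with no change 0 genes were called. Of 100 genes changed by 0.5 at day 21 only, the difference between days recovered 61, and within a cell type 60 of 100 genes changed by 1 were recovered.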

Results

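Sprouting and non-sprouting neurons, as the labels name them, were captured by laser from cortex of rats aged 2 months after a stroke, about 300 neurons of each type per animal. A fluorescent cholera toxin tracer (Alexa 488) was injected beside the infarct, and a tracer of another colour (Alexa 647) was injected at the same site 7 or 21 days later. Neurons were taken 7 days after the second tracer. RNA of both cell types of an animal was amplified in 2 rounds and hybridised together on a 2-colour rat array. Day 7 and day 21 were separate groups of 5 animals. Each animal had 2 arrays with the dyes swapped, which made 20 arrays from 10 animals. The animal is the replicate in all fits except the alternative that fits the 20 arrays. Every ratio below is sprouting over non-sprouting neurons of the same animal on the log2 scale. Median spot signal per array lay between 98.7 and 344.7 units in Cy5 and between 133.9 and 281.4 units in Cy3, over a local background of 40 to 45 and 29 to 45 units. Between 40.3% and 94.6% of the probes lay well above background in a channel of an array. The number of animals limits the precision, with a median standard error of 0.052 per day over 33089 genes.

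The 2 arrays of an animal ran in the labelled direction in 9 of the 10 animals. Across genes, which are not independent replicates, the ratios of both arrays correlated with Pearson r from 0.59 to 0.73 in the 5 day 7 animals. In the day 21 animals r was 0.33, 0.73, 0.68 and 0.56 in replicates 1, 2, 3 and 5, and -0.36 in replicate 4. With arrays centred on their median in place of loess the median r over the animals turned from 0.67 to -0.09. The standard deviation over genes of an animal's ratio, the mean of its 2 arrays, was 0.065 in day 21 replicate 4 and between 0.155 and 0.239 in the others. On single arrays it was 0.119 and 0.11 in that animal and between 0.172 and 0.264 in the others. Ratios of different animals shared little. The median r across genes was 0.01 between day 7 animals (-0.11 to 0.44) and 0.06 between day 21 animals (-0.01 to 0.22). It was 0.07 between a day 7 and a day 21 animal (-0.13 to 0.31). The mean ratios of the 2 days had r = 0.32 across genes and the same sign in 57.7% of them.

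**Figure D1:**
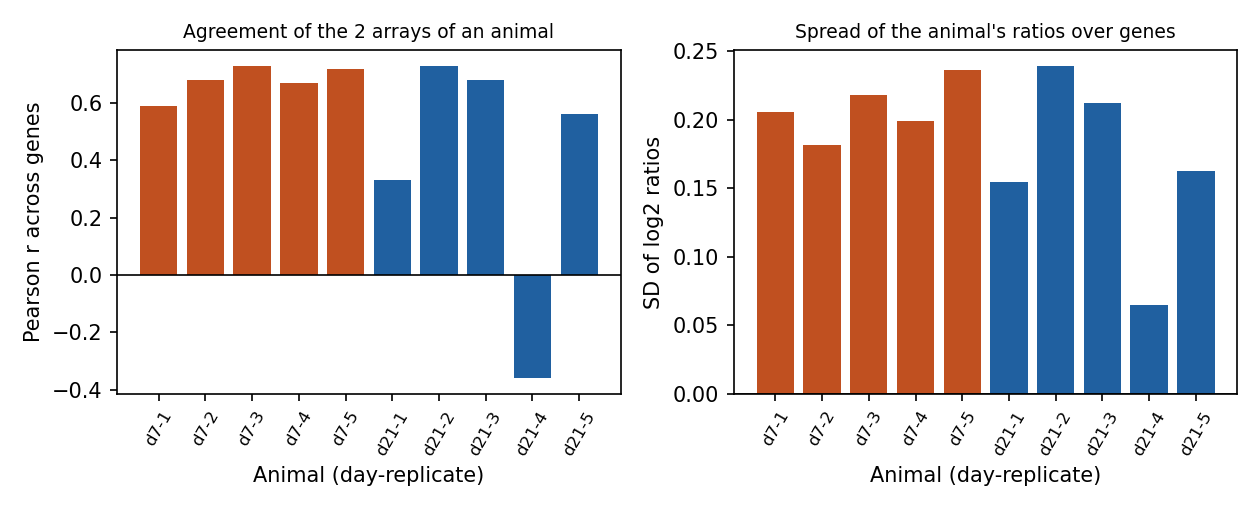
Left, Pearson r across genes between the log2 ratios of the 2 dye-swapped arrays of each animal, both turned to sprouting over non-sprouting; right, the standard deviation over genes of the animal's log2 ratios. Orange bars are day 7 animals and blue bars are day 21 animals; r lies between 0.33 and 0.73 except in day 21 replicate 4, at -0.36 with a standard deviation of 0.065, and with arrays centred on their median in place of loess the median r is -0.09.

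At day 7 the comparison asks which transcripts differ between neurons that sprout after stroke and neurons that do not. In sprouting neurons Stim2, a calcium sensor of the endoplasmic reticulum, was 1.34-fold higher (log2 ratio 0.42 ± 0.09, SD, n = 5), with its probes giving 0.1 and 0.42. Srp72, a subunit of the signal recognition particle, stood at 0.42 ± 0.16, Pik3r1, the regulatory subunit of phosphoinositide 3-kinase, at 0.41 ± 0.16, and Rasgrp1, a Ras activator, at 0.45 ± 0.13 (SD, n = 5 each). The serotonin receptor Htr7 was 1.68-fold lower (-0.75 ± 0.36, other probe -0.05), Lhx2, a transcription factor of cortical development, 1.38-fold lower (-0.47 ± 0.19), and Sntg2, a syntrophin, lay at -0.32 ± 0.12 (SD, n = 5 each). Each of these 7 genes had the same sign in all 5 animals, which the rule that names genes by p asks for. None of the 7 passed the correction (adjusted p = 0.221, and 0.279 for Lhx2). Prss22, a serine protease, was 1.55-fold higher (0.63 ± 0.3) and Nrip3 1.19-fold higher (0.25 ± 0.08), at adjusted p = 0.269 and 0.221 (n = 5 each, SD). By limma, 1 of 33089 genes passed, and 3137 had an unadjusted p under 0.05 (1490 higher and 1647 lower) where 1654 would be expected by chance. With the scanner software's own processed signals that count was 1700, and without each animal in turn it lay between 2562 and 4094. The gene that passed, RGD1311768_predicted, has no current symbol and was named here after its value was seen. It fell 1.31-fold (-0.39 ± 0.02, SD, n = 4, lower in 4 of 4 animals, adjusted p = 0.0263), while its other probe gave -0.02. It passed without day 7 replicate 5 or day 21 replicate 3, at nearly the same adjusted p (0.025 and 0.0248). Without any of the other 8 animals it lost the call. As it was measured in only 4 of the 5 day 7 animals, leaving out an animal without a value would test nothing. Its adjusted p was 0.102, 0.255, 0.15 and 0.25 without day 7 replicates 1 to 4. It was 0.0867, 0.08, 0.113 and 0.0947 without day 21 replicates 1, 2, 4 and 5. A fit of the 20 arrays with the animal as a random block has 17 residual degrees of freedom in place of 8. In it 403 genes passed (204 higher and 199 lower), among them 19 of the 20 genes named by the rule for this day. The fit counts the 2 arrays of an animal as partly separate, so 403 is not a count with the animal as the replicate. The rule took the smallest p in the same data, so the 19 are no separate evidence.

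Genes known for regrowth did not pass at day 7. Gap43, a growth cone protein, had a ratio of -0.24 ± 0.17 and Stmn2, a microtubule regulator, -0.02 ± 0.21 (SD, n = 5 each). The stress-induced transcription factors Atf3 and Jun lay at -0.3 ± 0.7 and -0.08 ± 0.26. The neurotrophin Bdnf lay at -0.32 ± 0.57 (other probe 0), Gdf10 at -0.14 ± 0.35, Igf1 at 0.15 ± 0.49 and its receptor Igf1r at -0.03 ± 0.1 (SD, n = 5 each). The Nogo receptor parts Rtn4r and Lingo1 lay at -0.03 ± 0.24 and 0.04 ± 0.09. The guidance molecules Epha4 and Efna5 lay at 0.12 ± 0.13 and 0.02 ± 0.14, and the chromatin remodeller Atrx at 0.45 ± 0.54 (SD, n = 5 each). Sprr1a was not analysed here. Of 44 growth-associated genes 23 were higher and 21 lower, with a median of 0.018 (adjusted p = 0.444). The median and the list test ask for a shift in 1 direction, so changes both ways can cancel. At an unadjusted p under 0.05 stood 11 of the 44 (6 higher and 5 lower), beside 3137 of 33089 over all genes. Adjusted over the list alone 0 passed.

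**Figure D2:**
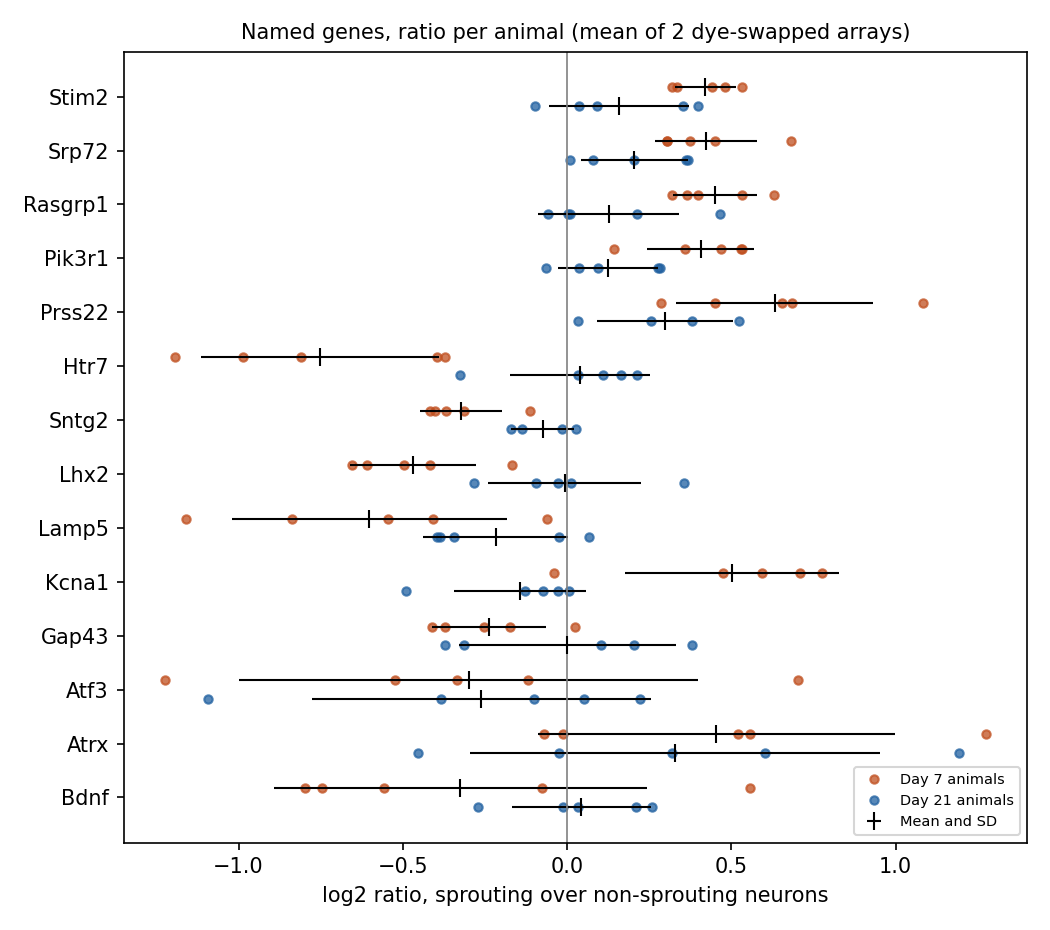
Log2 ratios of named genes (horizontal axis) in sprouting over non-sprouting neurons, where each point is an animal (orange, day 7; blue, day 21) and the cross gives the mean and standard deviation. At day 7 Stim2 lies at 0.42 ± 0.09 and Htr7 at -0.75 ± 0.36, while Gap43 lies at -0.24 ± 0.17 and Atrx spreads widely on both days.

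Of the 27 gene lists, 9 rose in sprouting neurons at day 7 against all other genes and none of the 9 calls held with an estimated correlation between genes. The estimate was 0.68 for oligodendrocyte, 0.5 for ribosomal and 0.15 for inflammatory and oxidative phosphorylation genes. It was 0.08 for deep layer, 0.03 for presynaptic and 0.02 for cytoskeleton genes. For growth-inhibitory (-0.02) and chromatin genes (-0.01) it lay below the preset 0.01, so correlation between members did not end these calls, here or between days. Ribosomal protein genes had 62 of 70 members higher, with a median of 0.105 under loess and -0.117 where arrays were only centred on their median (adjusted p = 4.43e-07, and adjusted p = 0.538 with an estimated correlation). Among them were Rpl3 (0.34 ± 0.26), Rps27a (0.27 ± 0.27) and Rps9 (0.23 ± 0.24, SD, n = 5 each). Oxidative phosphorylation genes had 33 of 46 higher, with a median of 0.047 that median centring turned to -0.155 (adjusted p = 0.00111, and adjusted p = 0.367 with an estimated correlation). Uqcrh and Uqcrc1 of respiratory complex III had ratios of 0.23 ± 0.19 and 0.19 ± 0.18 (SD, n = 5 each). Inflammatory and interferon genes had 33 of 47 higher with a median of 0.048 (adjusted p = 0.00111, and adjusted p = 0.367 with an estimated correlation). Their medians in the 5 animals were -0.06, 0.12, -0.04, 0.02 and 0.1, and those of microglial markers, a list that did not pass, had the same signs (-0.17, 0.48, -0.25, 0.09 and 0.02). The interferon-induced Rsad2 lay at 0.66 ± 0.75 with its other probe at -0.04, and the chemokine Cxcl10 at 0.68 ± 0.88 (SD, n = 5 each). Markers of oligodendrocytes, the myelinating glia, had 14 of 17 higher with a median of 0.289 (adjusted p = 0.0111, and adjusted p = 0.661 with an estimated correlation). Mbp of myelin had a ratio of 0.74 ± 1.17 and Mal 0.47 ± 0.52 (SD, n = 5 each). The oligodendrocyte medians of day 7 replicates 1 to 5 were -0.3, 0.2, -0.17, 0.69 and 0.86, and the ribosomal medians of the same animals -0.2, 0.04, 0.11, 0.12 and 0.39. With each animal's oligodendrocyte median as a covariate, a choice made after seeing the data, the ribosomal, inflammatory and oxidative phosphorylation lists no longer passed (adjusted p = 0.266, 0.232 and 0.124). Their medians went from 0.105 to 0.019, from 0.048 to 0.029 and from 0.047 to 0.039, with SDs over members of 0.09 and 0.1, 0.22 and 0.2, and 0.08 and 0.09. The calls ended as the mean moderated t of the members, less that of all other genes, fell from 1.14 to 0.3, from 0.9 to 0.45 and from 0.92 to 0.52. Without day 7 replicate 5 the ribosomal and inflammatory lists failed (adjusted p = 0.336 and 0.16). The oligodendrocyte list failed without day 7 replicate 4 or 5 (adjusted p up to 0.553).

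The growth-inhibitory signalling list, which holds myelin proteins, receptors of growth inhibitors and their targets, had 19 of 26 members higher at day 7 with a median of 0.049 (adjusted p = 0.0111, and adjusted p = 0.181 with an estimated correlation). Its medians in the 5 animals were 0.09, 0.04, 0.12, 0.06 and 0.05. An example is Ptprs, a receptor of proteoglycans (0.43 ± 0.39, SD, n = 5). The actin regulator Limk2 lay at -0.31 ± 0.17 with its other probe at 0.04. The list shares 3 members with the oligodendrocyte markers, Mbp, Mog and Mag, and without members held by other lists its adjusted p was 0.0214. Chromatin regulators had 22 of 36 higher with a median of 0.044 (adjusted p = 0.0209, and adjusted p = 0.181 with an estimated correlation). Kmt2a lay at 0.09 ± 0.05 and Smarcc1 at 0.15 ± 0.16 (SD, n = 5 each). Cytoskeleton genes had 31 of 51 higher, with a median of 0.031 that median centring turned to -0.079 (adjusted p = 0.0209, and adjusted p = 0.318 with an estimated correlation). The kinesin Kif5c had a ratio of 0.4 ± 0.35 and Map2 of dendrites 0.54 ± 0.57 (SD, n = 5 each). Presynaptic genes had 27 of 43 higher with a median of 0.028 (adjusted p = 0.0134, and adjusted p = 0.318 with an estimated correlation). Amph of vesicle endocytosis had a ratio of 0.21 ± 0.11 and Cplx1 of vesicle fusion 0.42 ± 0.42, while the calcium channel Cacna1b lay at -0.43 ± 0.21 with its other probe at 0.03 (SD, n = 5 each). Deep layer markers had 13 of 22 higher with a median of 0.028 (adjusted p = 0.0209, and adjusted p = 0.367 with an estimated correlation). Bcl11b lay at 0.67 ± 0.5 with its other probe at -0.02, and Pcp4 at 0.53 ± 0.64 (SD, n = 5 each). The medians of the 5 animals split for the cytoskeleton list (0.09, -0.01, 0.09, -0.02 and 0.03) and the presynaptic list (0.1, 0, 0.12, -0.01 and 0), each higher in 3 and lower in 2. They were higher in 5 of 5 animals for the chromatin list and in 4 of 5 for deep layers and oxidative phosphorylation. The deep layer call was lost without members shared with other lists (adjusted p = 0.178) and with the oligodendrocyte covariate (0.0842). With the covariate its median rose from 0.028 to 0.076 (SD over members 0.28 in both), and the unadjusted p went from 0.00697 to 0.0156, past the limit only after the correction over lists. It also failed without day 7 replicate 1 or 4 (adjusted p up to 0.138). With median centring the growth-inhibitory, chromatin, presynaptic, deep layer and oligodendrocyte calls ended (adjusted p = 0.485, 0.636, 0.512, 0.166 and 0.0564), as did that of the cytoskeleton list (0.23), while the ribosomal and oxidative phosphorylation lists passed as lower in sprouting neurons (0.00581 and 0.000252). The chromatin list failed without replicate 1 or 5 (up to 0.133), the cytoskeleton list without replicate 1 or 3 (up to 0.133) and the presynaptic list without replicate 3 (0.158).

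The other 18 lists did not pass at day 7. Without members shared with other lists, 9 lists passed, 8 higher and 1, from outside the 9 above, lower in sprouting neurons. Upper layer markers had 10 of 15 lower (median -0.044, adjusted p = 0.0934), with Lamp5 at -0.6 ± 0.42 and Cdh13 at 0.35 ± 0.28 (SD, n = 5 each). Members higher and adjusted p were 27 of 44 and 0.244 for axon guidance, 12 of 23 and 0.759 for chondroitin sulfate proteoglycans, 31 of 64 and 0.882 for growth factors, and 13 of 32 and 0.759 for immediate early genes. These values were 26 of 59 and 0.882 for glutamate and GABA receptors, 28 of 55 and 0.759 for ion channels, and 18 of 34 and 0.244 for heat shock. For the remaining gene lists they were 10 of 31 and 0.759 for apoptosis, 11 of 24 and 0.882 for cholesterol synthesis, and 27 of 52 and 0.889 for adhesion. Among cell type markers they were 10 of 18 and 0.759 for astrocytes, 11 of 19 and 0.759 for microglia, and 11 of 22 and 0.702 for endothelial and mural cells. They were 6 of 10 and 0.471 for blood, 10 of 21 and 0.889 for GABAergic interneurons and 11 of 22 and 0.889 for glutamatergic projection neurons. Kcna1, a potassium channel of axons, had a ratio of 0.5 ± 0.32 (n = 5, SD), with its probes at 0.5 and 0.88. The immediate early gene Egr2 lay at -0.74 ± 0.77 and the neuropeptide Vip at -0.93 ± 0.78 (SD, n = 5 each). Over all genes 0 list members passed by limma, and adjusted over the list alone 10 genes did. They were Limk2 among growth-inhibitory genes, Pdgfa among growth factors, Amph and Cacna1b among presynaptic genes and Kcna1 among ion channels. The others were Bcl11b, Lamp5 and Rspo1 among glutamatergic markers, and Lamp5, Lhx2 and Cdh13 among upper layer markers. Median, mean and test differed in sign in 7 of the 27 lists, none of which passed.

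**Figure D3:**
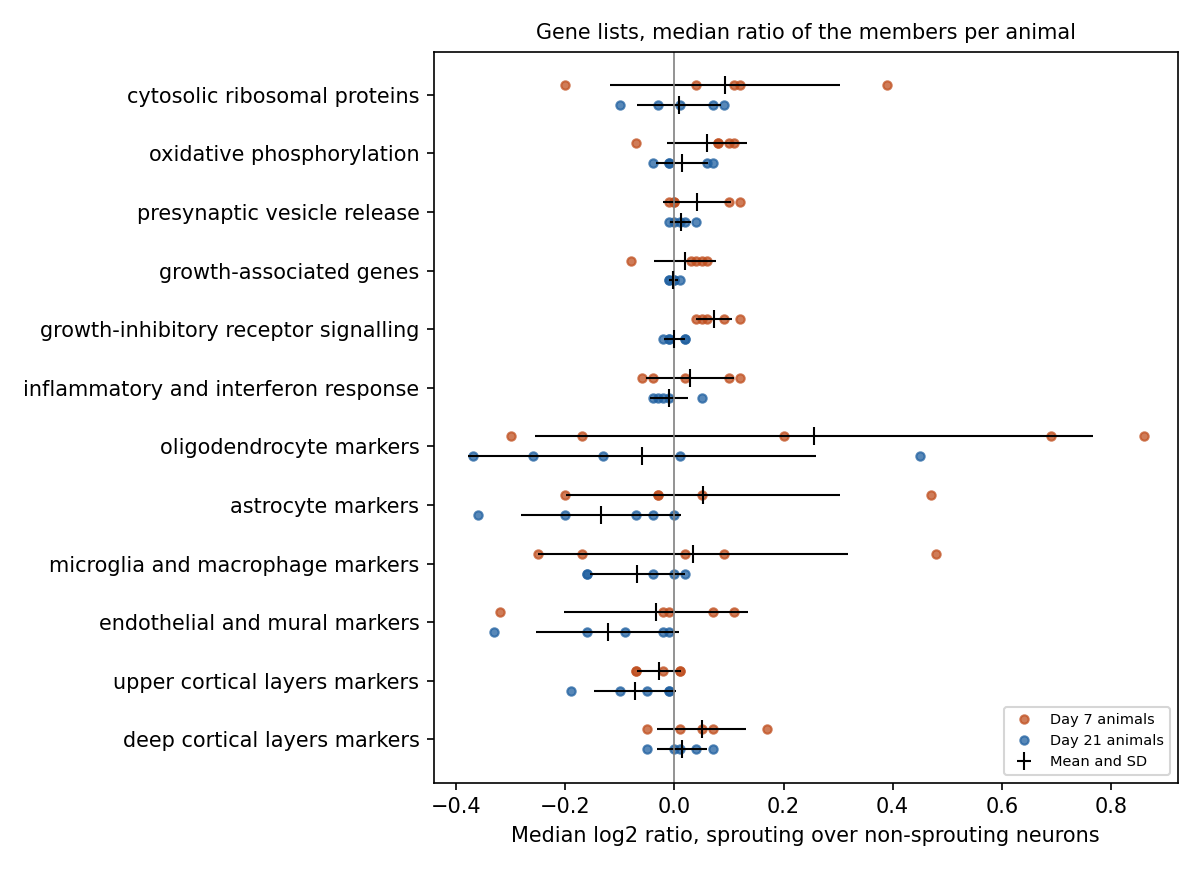
Median log2 ratio of the members of 12 gene lists (horizontal axis), where each point is an animal (orange, day 7; blue, day 21) and the cross gives the mean and standard deviation over animals. Oligodendrocyte markers range from -0.3 to 0.86 at day 7, the growth-inhibitory list lies between 0.04 and 0.12 in the 5 day 7 animals, and the ribosomal list, with a day 7 median over genes of 0.105, has -0.117 where arrays are only centred on their median.

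At day 21 the same question was asked of animals in which the second tracer came later. In sprouting neurons Plekhh2 stood at 0.25 ± 0.14 (other probe 0.02), the RNA-binding protein Syncrip at 0.2 ± 0.1 and Mtpn at 0.18 ± 0.1 (SD, n = 5 each). Fmnl1, a formin that acts on actin, lay at -0.31 ± 0.1 and the integrin Itgb6 at -0.23 ± 0.09. Kdelr1, a receptor of the secretory pathway, lay at -0.16 ± 0.08 and Aldh2, the mitochondrial aldehyde dehydrogenase, at -0.19 ± 0.09 (SD, n = 5 each). All had the same sign in 5 of 5 animals, as the rule that names genes by p asks, where replicate 4, with its near-equal channels and disagreeing arrays, was kept and counted. None of these genes passed (adjusted p = 0.84). By limma 0 genes passed, with 1920 at an unadjusted p under 0.05 (1132 higher and 788 lower). Without day 21 replicates 1, 2 or 3 that count was 1503, 1094 and 1379, below the 1654 expected by chance over all genes, and without replicates 4 or 5 it was 2166 and 2077. Gap43 lay at 0 ± 0.33, Jun at 0.17 ± 0.1, Atf3 at -0.26 ± 0.52, Stmn2 at -0.04 ± 0.14, Bdnf at 0.04 ± 0.21 and Atrx at 0.33 ± 0.62 (SD, n = 5 each). Igf1 lay at -0.02 ± 0.29, Igf1r at -0.04 ± 0.04, Lingo1 at -0.05 ± 0.08, Rtn4r at -0.05 ± 0.22 and Gdf10 at -0.13 ± 0.14 (SD, n = 5 each). Epha4 lay at 0.07 ± 0.12 and Efna5 at 0.01 ± 0.06 (SD, n = 5 each), which turned to -0.07 and -0.2 with the scanner software's own processed signals.

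Astrocyte markers fell in sprouting neurons at day 21, with 13 of 18 members lower and a median of -0.149 (adjusted p = 0.0177, and adjusted p = 0.985 with an estimated correlation). Aldoc of glycolysis had a ratio of -0.2 ± 0.18 and the glutamate transporter Slc1a3 -0.21 ± 0.16 (SD, n = 5 each). The list's medians in the 5 animals were -0.04, -0.07, -0.2, 0 and -0.36, and the call was lost without day 21 replicate 3 or 5 (adjusted p up to 0.214) and with the processed signals (0.0997). Without day 7 replicate 3 or day 21 replicate 2 or 4, 2 lists passed, and without day 21 replicate 1, 3 lists. Endothelial and mural markers had 15 of 22 lower (median -0.109, adjusted p = 0.0831), with the junction protein Esam at -0.27 ± 0.17 and the glucose transporter Slc2a1 at -0.28 ± 0.3 (SD, n = 5 each). Microglial markers had 14 of 19 lower (-0.066, adjusted p = 0.164) and upper layer markers 11 of 15 (-0.052, adjusted p = 0.164). The other 23 lists had adjusted p from 0.416 to 0.981, among them growth-associated genes with 22 of 44 higher (0.947) and ribosomal genes with 38 of 70 higher (0.947). The interneuron marker Pvalb lay at 0.34 ± 0.2 (SD, n = 5). No member passed over all genes and 0 passed adjusted over the list alone. Median, mean and test differed in sign in 9 lists, with medians within 0.019 of 0.

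With both days in a single mean over 10 animals, Srp72 lay at 0.31 ± 0.19 and the ceramide glucosyltransferase Ugcg at 0.26 ± 0.18 (SD, n = 10 each). The proton pump subunit Atp6v1a lay at 0.35 ± 0.25 and the AMPA receptor subunit Gria1 at 0.27 ± 0.19, and all 4 were higher in sprouting neurons of 10 of 10 animals, day 21 replicate 4 with its near-equal channels counted here and below. The rule that names genes by p asks for the same sign in every animal, so such counts are not separate evidence. Homer2, a scaffold of glutamate synapses, lay at -0.1 ± 0.07, Tm9sf2 at -0.25 ± 0.16 and the neuropeptide Y receptor Npy5r at -0.24 ± 0.21, lower in all 10 (SD, n = 10 each). None passed (adjusted p = 0.398). Atrx was higher in 6 of 10 animals (0.39 ± 0.56, n = 10, SD, adjusted p = 0.437) and Epha4 in 9 of 10 (adjusted p = 0.419), the latter with its day 21 mean turned below 0 by the processed signals. By limma 0 genes passed, with 3637 at an unadjusted p under 0.05 (1852 higher and 1785 lower) and a smallest adjusted p of 0.163. With 20 arrays and the animal as a random block 509 genes passed (375 higher and 134 lower), among them 11 of the 20 genes named by the rule. That fit counts the arrays of an animal as partly separate, and the rule took the smallest p in the same data. Neither count is separate evidence. With the oligodendrocyte covariate, chosen after seeing the data, 3 genes passed: Htr7 (-0.29), AI007835 (0.35) and AI102076 (0.41), the latter pair named after their values were seen.

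Over both days 4 of the 27 lists passed and none with an estimated correlation. Ribosomal genes had 54 of 70 higher with a median of 0.054, which median centring turned to -0.077 (adjusted p = 0.00164, and adjusted p = 0.841 with an estimated correlation). Oxidative phosphorylation genes had 32 of 46 higher with a median of 0.023, turned to -0.087 by median centring (adjusted p = 0.0329, and adjusted p = 0.644 with an estimated correlation). Presynaptic genes had 27 of 43 higher with a median of 0.028 (adjusted p = 0.0329, and adjusted p = 0.527 with an estimated correlation), as in Amph (0.15 ± 0.12) and Cplx1 (0.34 ± 0.32, SD, n = 10 each). Markers of upper cortical layers fell, with 11 of 15 lower and a median of -0.058 (adjusted p = 0.0482, and adjusted p = 0.527 with an estimated correlation). Lamp5 had a ratio of -0.41 ± 0.38, Lhx2 -0.24 ± 0.32 and Kitlg -0.42 ± 0.45 with its other probe at -0.03 (SD, n = 10 each). The medians of this list per animal gave p = 0.0234 in an exact sign-flip test, adjusted p = 0.369 over the lists. Over both days oligodendrocyte markers had 13 of 17 higher (median 0.082, adjusted p = 0.321) and astrocyte markers 12 of 18 lower (-0.049, 0.282). With median centring the ribosomal and oxidative phosphorylation lists passed as lower in sprouting neurons (adjusted p = 0.0176 and 0.00221). Median centring ended the presynaptic and upper layer calls (adjusted p = 0.76 and 0.122), and the latter was also lost with the processed signals (0.111) and without shared members (0.104). The ribosomal call was lost without day 7 replicate 5 (adjusted p = 0.479) and with the oligodendrocyte covariate (0.152), which also ended those of oxidative phosphorylation (0.133) and upper layers (0.0842). With the covariate the ribosomal median went from 0.054 to 0.024 and that of oxidative phosphorylation from 0.023 to 0.014 (SD over members 0.06 and 0.07, and 0.05 in both). That of upper layers stayed, from -0.058 to -0.057 (SD over members 0.18 and 0.17), and its call ended through the correction over lists (unadjusted p = 0.00715 and 0.0123). The presynaptic call was lost without day 7 replicate 3 or day 21 replicates 1, 2 or 5 (adjusted p up to 0.133). That of oxidative phosphorylation was lost without day 7 replicates 2 to 5 or day 21 replicates 1 or 3 (adjusted p up to 0.111), and that of upper layers without day 7 replicates 3 to 5 or day 21 replicates 1, 2 or 5 (up to 0.23). Beside 0 members passing over all genes, 8 genes passed adjusted over the list alone: Limk2, Amph, Gria1, Homer2, Lamp5, Kitlg, Lhx2 and Cdh13. Median, mean and test differed in sign in 5 lists, none of which passed.

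Whether the ratio itself differed between the days was tested directly. Htr7 went from -0.75 ± 0.36 at day 7 to 0.04 ± 0.21 at day 21, Gpr83 from -0.24 ± 0.22 to 0.24 ± 0.16 and Bfsp1 from -0.34 ± 0.2 to 0.11 ± 0.14. Olfm3, a secreted protein of neurons, went from 0.3 ± 0.16 to -0.15 ± 0.14 (SD, n = 5 each). The difference of the other probe was 0.03 for Htr7 and -0.14 for Olfm3. Among list members Egr2 differed between days by 1.09 ± 0.32, Rsad2 by -0.95 ± 0.31 (other probe 0), Pcp4 by -0.81 ± 0.27 and Kcna1 by -0.64 ± 0.15 (SE, n = 5 per day). None of these genes passed (adjusted p = 0.943). By limma 0 genes passed, with 1340 at an unadjusted p under 0.05 where 1654 would be expected by chance, and the smallest adjusted p was 0.506. That count was 3349 with scan day as a block, a fit that rests on day 7 replicates 4 and 5, and 1157 to 1979 without each animal in turn. With 20 arrays and the animal as a random block 4 genes passed: Htr7 (0.79), Olfm3 (-0.44), BF284864 (0.67) and TC525833 (0.45), the latter pair named after their values were seen. That fit counts the arrays of an animal as partly separate.

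As sets, 9 lists fell from day 7 to day 21, in the test of the difference between days, and none of the 9 held with an estimated correlation. Oligodendrocyte markers had 15 of 17 lower (median -0.318, adjusted p = 0.00229, and adjusted p = 0.571 with an estimated correlation). Astrocyte markers had 15 of 18 lower (-0.114, adjusted p = 0.0126, and adjusted p = 0.568 with an estimated correlation) and endothelial and mural markers 17 of 22 (-0.039, adjusted p = 0.019, and adjusted p = 0.568 with an estimated correlation). Inflammatory genes had 37 of 47 lower (-0.086, adjusted p = 0.000673, and adjusted p = 0.568 with an estimated correlation). Ribosomal genes had 61 of 70 lower with a median of -0.099, turned to 0.09 by median centring (adjusted p = 5.69e-05, and adjusted p = 0.625 with an estimated correlation). Oxidative phosphorylation genes had 31 of 46 lower with a median of -0.034, which median centring turned to 0.1 and whose test pointed the other way at a median of -0.01 with the processed signals (adjusted p = 0.0172, and adjusted p = 0.568 with an estimated correlation). Growth-inhibitory genes had 20 of 26 lower (-0.075, adjusted p = 0.019, and adjusted p = 0.225 with an estimated correlation). Rhob, a small GTPase, lay at 0.1 ± 0.21 at day 7 and -0.23 ± 0.24 at day 21 (SD, n = 5 each). The medians of the growth-inhibitory list per animal lay between 0.04 and 0.12 at day 7 and between -0.02 and 0.02 at day 21. They differed with p = 0.00794 in an exact permutation test, adjusted p = 0.214 over the lists. This is the smallest p that 5 against 5 animals allow, so the adjusted test could not pass for this list alone. Chromatin genes had 27 of 36 lower with a median of -0.035, turned to 0.023 by median centring (adjusted p = 0.0318, and adjusted p = 0.225 with an estimated correlation). Cytoskeleton genes had 34 of 51 lower with a median of -0.053, turned to 0.025 by median centring (adjusted p = 0.0405, and adjusted p = 0.568 with an estimated correlation). Among the marker lists only those of oligodendrocytes, astrocytes and endothelial and mural cells fell by this test. Those of microglia, blood, interneurons, glutamatergic neurons and cortical layers did not pass. Day 7 replicates 4 and 5, with the highest oligodendrocyte medians (0.69 and 0.86), were also the animals without which the calls went from 9 to 2 and to 0.

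Arrays were scanned on 5 days, of which scan days 4 and 5 held both arrays of day 7 and of day 21 animals, with 1 against 2 animals and 1 against 1. Within scan days 4 and 5 the day 21 minus day 7 list medians were -1.18 and -0.82 for oligodendrocyte, -0.6 and -0.41 for astrocyte and -0.2 and -0.44 for endothelial markers. They were -0.4 and -0.15 for ribosomal, -0.06 and -0.09 for oxidative phosphorylation, -0.13 and -0.05 for inflammatory, -0.05 and -0.08 for growth-inhibitory, 0 and -0.04 for chromatin and -0.03 and 0.05 for cytoskeleton genes. The day 7 animals were replicate 5 on scan day 4 and replicate 4 on scan day 5, those with the highest oligodendrocyte medians. With scan day as a block, a fit that rests on the same 2 day 7 animals, the chromatin and cytoskeleton calls ended with their medians turned to 0.004 and 0.021 (adjusted p = 0.422 and 0.711), 10 lists passed, and the oligodendrocyte median was -1.03. Each of the 9 calls was lost without day 7 replicate 5, with adjusted p up to 0.439 for ribosomal and 0.113 for inflammatory genes. Without day 7 replicate 4 the oligodendrocyte (up to 0.272), astrocyte (up to 0.272, and without day 21 replicate 5) and endothelial calls (up to 0.253, and without day 7 replicate 2 or day 21 replicate 5) were lost as well. So were those of the growth-inhibitory list (up to 0.113, and without day 7 replicate 3), and the chromatin list (up to 0.123, and without day 7 replicate 1 or day 21 replicates 1 or 5). The same held for oxidative phosphorylation (up to 0.124, and without day 7 replicates 2 or 3 or day 21 replicates 2 or 5) and the cytoskeleton list (up to 0.232, and without day 7 replicates 1 or 3 or day 21 replicates 1, 3 or 4). With the processed signals and with median centring only the inflammatory (adjusted p = 0.0229 and 0.00066) and oligodendrocyte calls (0.0249 and 0.00111) of the 9 remained, and with the oligodendrocyte covariate, which ends the oligodendrocyte call by construction, only that of the cytoskeleton list of the other 8 (0.029), which ended with replicate number as a block (0.0572). With the covariate the growth-inhibitory median stayed, from -0.075 to -0.071 (SD over members 0.19 and 0.17), and the chromatin median went from -0.035 to -0.049 (0.11 in both). Their calls ended through the correction over lists, with unadjusted p = 0.0117 and 0.00976. The ribosomal median went from -0.099 to -0.017 (0.1 and 0.11), the inflammatory from -0.086 to -0.044 (0.24 and 0.22) and that of oxidative phosphorylation from -0.034 to -0.015 (0.09 and 0.1). Astrocyte markers went from -0.114 to -0.048 (0.14 and 0.13) and endothelial markers from -0.04 to 0.004 (0.17 and 0.16), over the members measured in all 10 animals. The other lists did not pass, the nearest being deep layer and microglial markers (adjusted p = 0.0697 each). Median, mean and test differed in sign in 6 lists, none of which passed, and 0 members passed over all genes or adjusted over the list alone.

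Between the days the level of each cell type was compared on its own, across arrays. In sprouting neurons C1ql3, a secreted synaptic protein, had a log2 signal of 12.08 ± 0.34 at day 7 and 13 ± 0.22 at day 21 (SD, n = 5 each). It differed by 0.92 ± 0.17 and Nsf, an ATPase of vesicle fusion, by 0.9 ± 0.21 (SE, n = 5 per day). Hbb, a haemoglobin chain, differed by -0.72 ± 0.1, Abhd3 by -0.92 ± 0.13 and Ndp, a secreted vascular growth factor, by -0.77 ± 0.12 (SE, n = 5 per day). In non-sprouting neurons Nsf differed by 1.06 ± 0.22 and Kcnip1, a potassium channel subunit, by 0.77 ± 0.11 (SE, n = 5 per day). Rbm27 differed by -0.85 ± 0.13, the receptor Ret by -0.77 ± 0.14 and Crhr1, a receptor of corticotropin-releasing hormone, by -0.75 ± 0.14. None passed, with adjusted p from 0.174 to 0.371 in sprouting and of 0.408 in non-sprouting neurons for these genes. By limma 0 genes passed in either cell type, with 2918 at an unadjusted p under 0.05 in sprouting (827 higher and 2091 lower at day 21) and 2966 in non-sprouting neurons (823 and 2143). Without day 7 replicate 5 these counts were 5898 and 6254, and without each other animal in turn they lay between 1830 and 3427 and between 1907 and 3746. The median over all genes shifted by -0.05 and -0.04 in sprouting and non-sprouting neurons, and by -0.18 and -0.14 with the processed signals. Days and scan days overlap in only part of the animals, and with scan day as a block 0 genes passed, with 1515 and 713 at an unadjusted p under 0.05.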

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

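Chosen only after the results were seen were the tests of a missed dye swap, of equal RNA in both channels, of unequal oligodendrocyte RNA and of a change shared by all day 7 animals. The tests of low signal, of a dye bias that follows brightness and of regrouped animals were chosen before.

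In day 21 replicate 4 the channels were nearly equal, and the ratios of its 2 arrays correlated at -0.36 across genes. The standard deviation of their average was 0.065, against 0.155 to 0.239 in the other 9 animals, and the negative correlation itself lowers it. On its single arrays the standard deviation was 0.119 and 0.11, against 0.172 to 0.264 in the others. With a difference as large as in the others, a missed swap would leave 206 to 1332 genes past 0.5 in the same dye direction on both arrays. That is the range the others show in the turned direction, and 13 were found. This argues only against a missed swap of so large a difference. The low count follows from the small spread, so a missed swap of a small difference stays open. The negative correlation after turning goes with it. Low signal is argued against by the brightest genes, with a standard deviation of 0.041 in this animal and 0.186 to 0.335 in the others. The same RNA, or an even mixture, in both channels stays open: 0 genes were past 0.5 in the turned direction on both arrays, but that count follows from the small spread itself and decides nothing. A small difference between the cell types of this animal stays open as well and was not tested.

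Oligodendrocyte markers, higher in sprouting neurons at day 7, were not shared by the animals: their medians were above 0 in 3 of 5, with -0.3 and -0.17 in replicates 1 and 3, which argues against a change common to all sprouting neurons of that day. The list's median was 0.271 over the 16 of its 17 tested members that were measured in all 10 animals. It exceeded those of random lists of like brightness (-0.066 to 0.058 for the central 95%, percentile 100). This argues against a dye bias that follows brightness and is left after loess. The random lists came from the same loess ratios, so loess itself was not tested. Unequal amounts of oligodendrocyte RNA in the captures of an animal predict that the markers move together. Over 10 animals the markers of the list, 5 of whose 19 genes stand on another list, followed the mean of the others with a median r of 0.86 (random lists up to 0.33 at the same limit). Markers of 1 cell type would move together under other explanations too, so this does not favour unequal amounts over them. Mbp, an abundant myelin transcript, ranged widely (0.74 ± 1.17, SD, n = 5). Whether glial cell bodies or processes were captured with the neurons was not tested. A difference of the tissue around sprouting neurons stays open and was not tested either.

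Ribosomal protein genes, higher at day 7 under loess, exceeded random lists of like brightness (0.105 against -0.014 to 0.048, percentile 100). The random lists came from the same loess ratios and had a median of 0.017. They argue only against a bias of brightness left after loess as the source of the whole shift, and cannot test loess itself. Without loess the ribosomal list turned to -0.117 and passed as lower by camera (adjusted p = 0.00581). Over 10 animals the ribosomal median followed that of the oligodendrocyte markers (Pearson r = 0.73, permutation p = 0.01, adjusted p = 0.02 over 2 relations, Spearman rho = 0.58, permutation p = 0.088). Without the 2 animals farthest from the median r was 0.37, so the relation rests on those animals, and within days it was 0.82 and 0.3, in 5 animals each. This relation cannot tell whether oligodendrocyte RNA in the captures accounts for part of the shift. A change in sprouting neurons stays open, with 4 of the 5 day 7 animals above 0.

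The following differences between days rest on camera with a preset correlation, and none passed with an estimated one. Day 21 minus day 7 medians were -0.32 for oligodendrocyte markers, -0.11 for astrocyte markers, -0.04 for endothelial and mural markers, -0.07 for growth-inhibitory signalling and -0.09 for inflammatory genes. They were -0.1 for ribosomal genes, -0.05 for cytoskeleton genes, -0.04 for chromatin regulators and -0.03 for oxidative phosphorylation, directions that median centring turned to 0.09, 0.025, 0.023 and 0.1. With scan day as a block the cytoskeleton and chromatin medians were 0.021 and 0.004.

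Of 200 groups of animals 11 held an animal that stood apart from the others by Dixon's criterion, about what chance gives at 1 in 20 groups. Among list medians at day 7, growth-associated genes lay at -0.08 in replicate 3 (others 0.03 to 0.06) and endothelial markers at -0.32 in the same animal (-0.02 to 0.11). In day 7 replicate 1 immediate early genes lay at 0.24 (-0.1 to -0.03) and oxidative phosphorylation at -0.07 (0.08 to 0.11). Among genes, Rhob lay at 0.47 (-0.06 to 0.07) and Rps27a at -0.21 (0.29 to 0.44) in day 7 replicate 1, and Pdgfa at 0.04 (0.23 to 0.31) in day 7 replicate 4. At day 21, Pdgfa lay at -0.18 (0.02 to 0.09) and Cacna1b at 0.59 (-0.1 to 0.02) in replicate 2, and Kcna1 at -0.49 (-0.13 to 0) and Uqcrh at 0.21 (-0.03 to 0.02) in replicate 3.

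Regrouped animals were counted by genes at an unadjusted p under 0.05. Over both days 1 of 100 sign changes of whole animals, the real one, reached 3637 genes (highest other 3030). This argues against chance as the source of the excess but does not exclude it, and 0 genes passed. The real count was 2764 with the processed signals, and 2848 and 2805 without day 21 replicates 1 and 2, settings whose sign changes were not counted. Within a day the 16 sign changes are too few for a share under 0.05: at day 7, 2 reached 3137 (highest other 3996) and 4, the real one included, passed 1 gene, and at day 21, 1 reached 1920 (highest other 1843). For the difference between days 60 of 100 splits gave 1340 genes or more (highest other 3467), and chance cannot be excluded. For day 21 against day 7 within sprouting neurons 14 of 100 splits gave 2918 or more (highest other 8625), and within non-sprouting neurons 16 of 100 gave 2966 or more (8606), so chance cannot be excluded there either. The days passed 0 genes, and in each cell type 3 of 99 other splits passed any. The highest, 475 and 148, came from the split by day with day 7 replicate 5 and day 21 replicate 4 exchanged, which had arrays of scan days 3, 4 and 5 on both sides. This points to a structure of the samples whose source was not tested.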

How the results depend on the processing

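Alternatives chosen only after the data were seen are the oligodendrocyte covariate, lists without shared members, scan day and replicate number as blocks for lists, scan day and a threshold of 0.1 for levels within a cell type, and other processing for the dye-swap agreement. The cause of the changes below was not tested unless named. At day 7 the 1 gene that passed became 0 with the processed signals, median centring, the mean of probes, moderation with a trend and a fit per day, and 0 to 1 without each animal in turn. With 20 arrays and the animal as a random block (animal correlation 0.58, 17 residual degrees of freedom in place of 8) 403 genes passed at day 7, 509 over both days and 4 in the difference. These counts take the arrays of an animal as partly separate, not the animal as the replicate. With the oligodendrocyte covariate 3 passed over both days, and at day 7 the gene that passed was Htr7 (-0.58), another gene, while RGD1311768_predicted kept its ratio (-0.38 against -0.39) at adjusted p = 0.0555. At day 21 and within each cell type 0 genes passed under every alternative run, as in leaving out each animal for both days and the difference.

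Lists passing at day 7 went from 9 to 0 with an estimated correlation, 4 with median centring (1 higher and 3 lower), 4 with the oligodendrocyte covariate (which ends the oligodendrocyte call by construction, here and in the difference) and 5 to 10 without each animal. At day 21 the 1 became 0 with an estimated correlation and with the processed signals, 3 with median centring and 0 to 3 without each animal. Over both days the 4 became 0 with an estimated correlation, 7 with the processed signals, 2 with the covariate and 1 to 6 without each animal. In the difference the 9 became 0 with an estimated correlation, 2 with the processed signals, 2 with median centring, 1 with the covariate and 0 to 9 without each animal. Median centring turned list medians to -0.117 (ribosomal), -0.155 (oxidative phosphorylation) and -0.079 (cytoskeleton) at day 7, to -0.077 and -0.087 (ribosomal and oxidative phosphorylation) over both days, and in the difference to 0.09, 0.1 and 0.025 for the 3 and to 0.023 for chromatin genes. There the processed signals turned the test of oxidative phosphorylation at a median of -0.01, scan day as a block turned the chromatin and cytoskeleton medians to 0.004 and 0.021, and the covariate that of endothelial markers to 0.004. The agreement of dye-swapped arrays, a median r of 0.67, was 0.26 with the processed signals and -0.09 with median centring. With scan day as a block Stmn2 and Igf1r differed by 0.25 and 0.1 between days, and with the processed signals Epha4 and Efna5 lay at -0.07 and -0.2 at day 21, all 4 reversed.

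With replicate number as a block in the difference 0 genes passed, and 8 lists. The numbers do not pair the animals: over replicates 1 to 5, r across genes between animals of the same number was -0.05, 0.01, 0.08, 0.01 and -0.06. The same number was never the best match. Scan day as a random block had a correlation of -0.03. Of 4890 alternative values of named genes, 4823 counted as unchanged, 14 no longer passed, 49 newly passed and 4 reversed. A change of sign counted as reversed only where the gene passed in either fit or moved by more than an SD between animals, estimated from its standard error. Smaller changes of sign around 0 stand among the other counts, so the 4823 need not all have kept direction. Signal over background limits dim probes: on 1 array only 40.3% of probes lay well above background in a channel. No filter or a stricter one on dim probes left the counts of genes at 1, 0, 0 and 0.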

Other observations

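The test of an upper layer deficit below was chosen after the result was seen. Over both days the list of interneuron markers did not pass (9 of 21 members higher, adjusted p = 0.958). Among its members Vip lay at -0.6 ± 0.71, lower in 9 of 10 animals. Pvalb lay at 0.25 ± 0.28 and higher in 7, and Nxph1 at 0.28 ± 0.26 and higher in 8 (SD, n = 10 each, adjusted over all genes none passed). Among glutamate receptors Grm3 lay at 0.35 ± 0.42 beside Gria1 at 0.27 ± 0.19 and Homer2 at -0.1 ± 0.07, and the list had 25 of 59 members higher (adjusted p = 0.886). Deep layer markers over both days had 12 of 22 higher with a median of 0.047 (adjusted p = 0.186).

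A hypothesis was that lower upper layer markers in sprouting neurons may come from capture in deeper layers, in which case the medians of upper and deep layer markers should go opposite ways over animals. Over the 10 animals they had Pearson r = -0.14 (permutation p = 0.687, adjusted p = 0.687 over 2 relations) and Spearman rho = -0.31 (permutation p = 0.388), and r = -0.33 without the 2 animals farthest from the median. Within days r was -0.53 and -0.12, in 5 animals each. The relation is too weak at this number of animals to tell, and the capture depth stays open.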
